A study of Nasonia vitripennis and Nasonia giraulti with 12 samples.

How the data were processed

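Whole-body RNA of 24 h adult wasps was measured in 12 libraries, 3 each from females and males of Nasonia vitripennis and Nasonia giraulti. Per the labels' protocols, each library was made from a pool of 10 animals with 2 ug of total RNA as input and a TruSeq version 2 kit, and the replicates were independent batches for each species and sex. The authors deposited estimated counts per gene, not scaled to library size, in a single table of 24337 genes and 12 libraries. CASAVA 1.8.2, FastQC, Trimmomatic, TopHat2 2.0, Cufflinks 2.1.0, HTSeq, bedtools and edgeR are named in the submitters' processing notes, without the role or order of each. The genome build and the annotation are not given in the sources used here. Nor is it known whether both species were aligned to the same reference. All 24337 genes carry identifiers that start with Nasvi2EG, in a single set used for both species. A gene that this set lacks cannot appear, so counts of genes without reads in a species need not be even between the species. Counts that depend on alignment to a reference can be lower in the species that is farther from it, and the test of a species difference cannot tell this from expression.

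As deposited, 3372 genes (13.9%) held a fractional value in at least 1 library. Of 958 isolated pairs of adjacent genes of this kind, 918 summed to whole counts in each library, within 0.02 reads plus a share of 2e-05 of the sum, so reads were divided between neighbouring rows. Such genes are marked in the report as sharing reads and their levels as uncertain. Counts were rounded to whole numbers before testing. No row lacked a gene name, and no column of per-sample values was left unused. None of the identifiers matched the name table used here, which holds 15501 genes of another annotation (0 matched). The gene lists fixed beforehand, their set tests and the test of neighbouring genes along the genome were therefore not run, and at most 2 identifiers per direction of a comparison are printed. Nasvi2EG000206, the one printed for the species difference in males, was chosen after its values were seen and not by the rule.

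Samples were grouped by the species and sex in the labels. Genes were kept with the filterByExpr function of edgeR by group (minimum count of 10), which left 16536 genes, 2763 of them (16.7%) with fractional values. Libraries were scaled with trimmed-mean factors (TMM). All 12 libraries entered a single quasi-likelihood fit with a mean per group (edgeR 4.0.16 in R 4.3.3, robust). Contrasts were males against females in each species, N. giraulti against N. vitripennis in each sex, and the difference of the sex effects. P-values were adjusted by Benjamini and Hochberg, and genes past 0.05 were called. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. Means and SDs are of TMM-scaled CPM. Principal components were computed from centred log2 CPM with a prior count of 2.

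The genes named in the text were chosen by a rule written before the data were examined. For each sex contrast and for the interaction these were the 2 with the highest and the 2 with the lowest log2 fold change among genes past 0.05, whose libraries did not overlap between the groups and whose higher group had a mean of at least 10 CPM. Where a group had 0 reads, the ratio is given as a bound against 3 counts over its libraries. Other ratios of pooled counts carry an exact binomial 95% interval. For groups with 0 reads the lower end of that interval is smaller than the bound, for example 1365 against 1680 for Nasvi2EG010600 in N. vitripennis. Intervals and floors cover counting error only.

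Depth was 23763596 to 51374887 counts per library, and a floor of 3 counts corresponds to 0.0584 to 0.126 CPM in a single library. Replicate libraries differed by more than sampling noise, with chi-square values per degree of freedom from 40.06 to 271, so none was the same library sequenced again, which does not exclude separate preparations of a shared sample, and their log2 CPM correlated with r from 0.955 to 0.991 across genes. The common dispersion was 0.111, a biological coefficient of variation of 33.3%.

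Whether the replicate numbers pair libraries across groups was checked before the fits were compared. Deviations of each library from its group mean were correlated between groups. All 18 pairs with the same number had r between 0.20 and 0.708, the 36 other pairs had r from -0.57 to 0.325, and 10 of the 12 libraries correlated best with their own number in each other group. The pairing thus comes from the data, and the labels do not say that a number marks a shared batch. The fit without the block is the main result, as fixed beforehand, and the fit with the replicate number as a block is an alternative. It lowered the common dispersion to 0.0477.

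Alternatives were the size factors of DESeq2, upper-quartile scaling, library size alone, no filter on low counts, a mean of at least 1 CPM, the Wald test of DESeq2 1.42.0, only the compared groups in the fit, the replicate block, a test against a 2-fold change, a fit that was not robust and leaving out each replicate. Added after the data were seen were fits without genes holding fractional counts and with the 8 libraries numbered 2 and 3. The test was run on simulated counts with 200 changed genes. For the sex difference in N. vitripennis it recovered 66.7% of genes changed 4-fold and 5.97% of those changed 2-fold, and for the interaction 36.4% and 1.49%. False calls made up 3.92% and 7.41% of the calls of these simulations, and over all 5 comparisons 3.64% to 8.57%, the highest for the species difference in females. The changed genes all had a mean of at least 1 CPM, so lower genes were not covered. The p-value needed for a call also depends on how many genes change. With 10745 genes called between the sexes of N. vitripennis, these shares need not hold for the real comparisons. Figures were drawn with matplotlib 3.10.9.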

Results

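Messenger RNA was sequenced from whole bodies of adult jewel wasps, 24 h after they left the pupal case, in a pair of closely related parasitoid species, Nasonia vitripennis (strain AsymCX) and Nasonia giraulti (strain R16A). Each library came from a pool of 10 animals of a single sex. There were 4 groups, females and males of each species, with 3 libraries per group, described in the labels as independent batches. In these wasps males develop from unfertilised eggs and are haploid, and females are diploid. The files held a read count for each of 24337 genes in each of the 12 libraries. Total counts ran from 23763596 to 51374887 per library. They lay between 24516522 and 47509108 in N. vitripennis females, between 23763596 and 51374887 in N. vitripennis males, between 32463168 and 39045479 in N. giraulti females and between 26494193 and 39597569 in N. giraulti males, and the library numbered 1 was the deepest in each group. Genes are given by the identifiers in the file, because the name table used here held none of them, so what a gene encodes is not stated below.

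Sex separated the libraries more than species did. The first principal component of the log2 scaled read count (CPM) of the 16536 tested genes held 56.5% of the variance, and 98.1% of its own variance lay between the sexes. The second component held 28.1%, and 98.9% of it lay between the species. Component 3, with 5.38%, followed the replicate number, with the libraries numbered 1 apart from those numbered 2 and 3 in each of the 4 groups. Summed over all tested genes, sex accounted for 55.7% of the variance, species for 28.3%, the dependence of the sex difference on species for 4.56% and the replicate number for 6.64%.

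**Figure D1:**
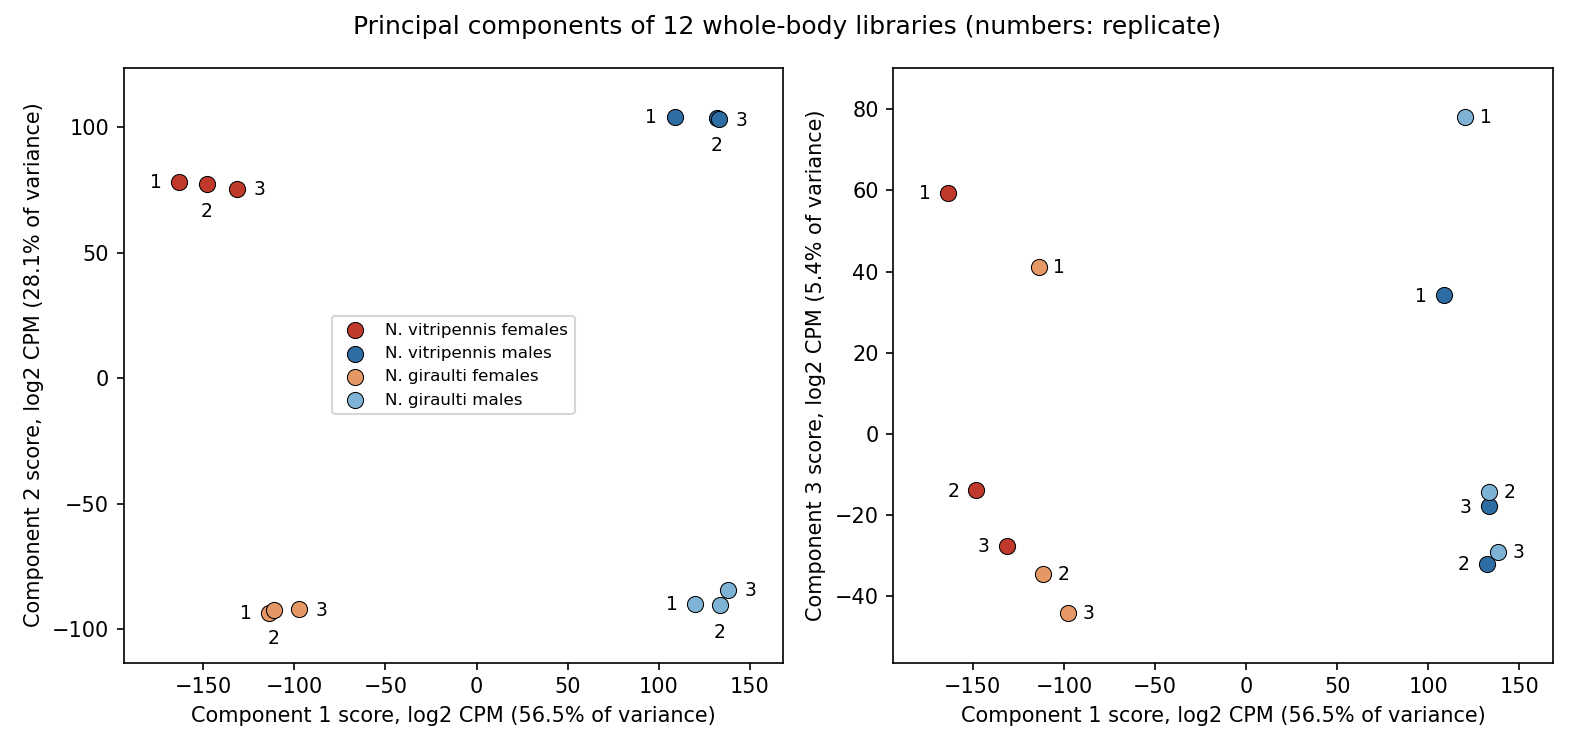
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with the share of variance on each axis. Each point is a library, the colour gives species and sex, and the number beside it is the replicate. Females and males lie at opposite ends of component 1 (56.5%), the species at opposite ends of component 2 (28.1%), and the libraries numbered 1 lie above the others on component 3 (5.38%).

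The first comparison asked which genes differed between the sexes of N. vitripennis. At this stage 5385 genes were higher in males and 5360 were higher in females, together 64.98% of the genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per sex). Of these, 4826 genes were at least 2-fold higher in males and 4495 at least 2-fold higher in females. The largest differences lay more often on the female side, with 1117 genes at least 10-fold higher in females against 506 at least 10-fold higher in males. The genes at least 2-fold higher in males took 48.4% ± 0.964 (SD, n = 3) of all counts in males and 10.3% ± 1.79 in females. Those at least 2-fold higher in females took 55.2% ± 2.42 of all counts in females and 13.1% ± 0.917 in males. These shares describe genes that were picked on the same libraries and are not a separate test. Whole bodies were measured, so in both species a sex difference cannot be told from a difference in the share of an organ between the sexes.

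The calls were spread unevenly over expression levels. These levels are means over all libraries, so a gene almost without reads in a sex or species falls lower for that reason. In the quartile of genes with the lowest mean expression, 1582 genes were higher in males and 487 in females. In quartile 3 of expression 992 were higher in males and 1984 in females, and in the highest quartile 1122 and 1791. The 10 most abundant genes of each library held 11.03% ± 1.60 (SD, n = 3) of counts in N. vitripennis males and 4.64% ± 0.297 in females, and the corresponding values in N. giraulti were 11.2% ± 0.765 and 4.85% ± 0.286. The most abundant gene of N. vitripennis males, singled out after its values were seen, held 4.58% ± 1.56 of counts in males and 0.00606% ± 0.00218 in females. Its log2 fold change of males over females was 9.47 (SE 0.58) in N. vitripennis and 9.44 (SE 0.58) in N. giraulti, with edgeR adjusted p of 2.38e-08 and 3.07e-08.

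By the rule fixed beforehand, the genes named for N. vitripennis males were Nasvi2EG010600 and Nasvi2EG012314. Nasvi2EG010600 stood at 59.0 CPM ± 32.9 (SD, n = 3) in males and had 0 reads in the 3 female libraries, at least 1680-fold higher in males against a floor of 3 counts over the group (edgeR adjusted p = 8.00e-08). Nasvi2EG012314 stood at 35.1 CPM ± 6.70 in males with 0 reads in females, at least 1166-fold higher (edgeR adjusted p = 8.07e-08). It holds fractional counts, so part of its reads is shared with another gene and its level is uncertain. On the female side, Nasvi2EG015109 had 53.2 CPM ± 10.1 in females and 3 reads in all male libraries together, a ratio of 1735 with a 95% counting interval from 593 to 8416 (edgeR adjusted p = 6.38e-09). Nasvi2EG000668, which also shares reads, had 10.9 CPM ± 7.62 in females and 0 reads in males, at least 402-fold higher in females (edgeR adjusted p = 0.000729). Scaling moved the balance of directions: 50.12% of the calls were higher in males with trimmed-mean (TMM) scaling and 65.53% with upper-quartile scaling. It turned toward females with no filter on low counts (5091 and 5521 genes), in a test against a 2-fold change (2775 and 3429), at a mean of at least 1 CPM, in the 8 libraries numbered 2 and 3 and without each single replicate.

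The same comparison in N. giraulti gave 4954 genes higher in males and 4447 higher in females, 56.85% of the genes tested. At least 2-fold differences were found in 4212 genes toward males and 3583 toward females, and at least 10-fold differences in 451 and 932. Genes at least 2-fold higher in N. giraulti males took 49.4% ± 2.27 (SD, n = 3) of counts in males and 15.2% ± 0.760 in females, again on the libraries that picked them. Nasvi2EG012314 was named in this species too, at 19.7 CPM ± 2.76 in males with 0 reads in females, at least 788-fold higher in males (edgeR adjusted p = 1.33e-07). Nasvi2EG013662 stood at 12.9 CPM ± 4.02 in males with 0 reads in females, at least 492-fold higher (edgeR adjusted p = 6.23e-07). Nasvi2EG004214 stood at 43.2 CPM ± 19.9 in females with 0 reads in males, at least 1245-fold higher in females (edgeR adjusted p = 6.60e-07). Nasvi2EG019966, which shares reads with another gene, had 26.1 CPM ± 9.27 in females and 0 reads in males, at least 769-fold higher in females (edgeR adjusted p = 0.0102). Its call was lost with the replicate number as a block (adjusted p = 0.0982), with no filter on low counts (0.0554) and in the 8 libraries numbered 2 and 3 (0.186), within a range of 2.03e-05 to 0.186 over the alternatives. Of the calls in N. giraulti, 52.7% were higher in males with TMM scaling, 65.02% with upper-quartile scaling and 40% with library size alone.

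The sex differences were then compared between the species, which share no library in these contrasts. There were 3732 genes higher in males in both species, where lists independent of each other would share 1613.3. Another 3985 genes were higher in females in both, where independent lists would share 1441.5. The odds ratios of these overlaps were 18.3 and 67.2, and the p-values of Fisher's exact test (two-sided) were too small for the software to represent. Of the 7895 genes called in both species, 97.7% had the same direction. At least 10-fold differences in both species were found in 284 genes toward males and 738 toward females. Across the 16536 genes the log2 fold changes of the 2 species had a Pearson correlation of 0.825 and a Spearman correlation of 0.795, and genes are not independent replicates. The remaining 178 genes were called in opposite directions. Of these, 112 were higher in females in N. vitripennis and in males in N. giraulti, and 66 the reverse. The 112 include Nasvi2EG023757, called higher in N. giraulti males on 3 reads against 0 in N. giraulti females (edgeR adjusted p = 0.0441). The lower counting bound of that ratio was 0.547, so an opposite call need not mean a reversed sex bias. In the test against a 2-fold change, 37 genes had opposite directions. With the replicate number as a block, 305 genes had opposite directions.

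**Figure D2:**
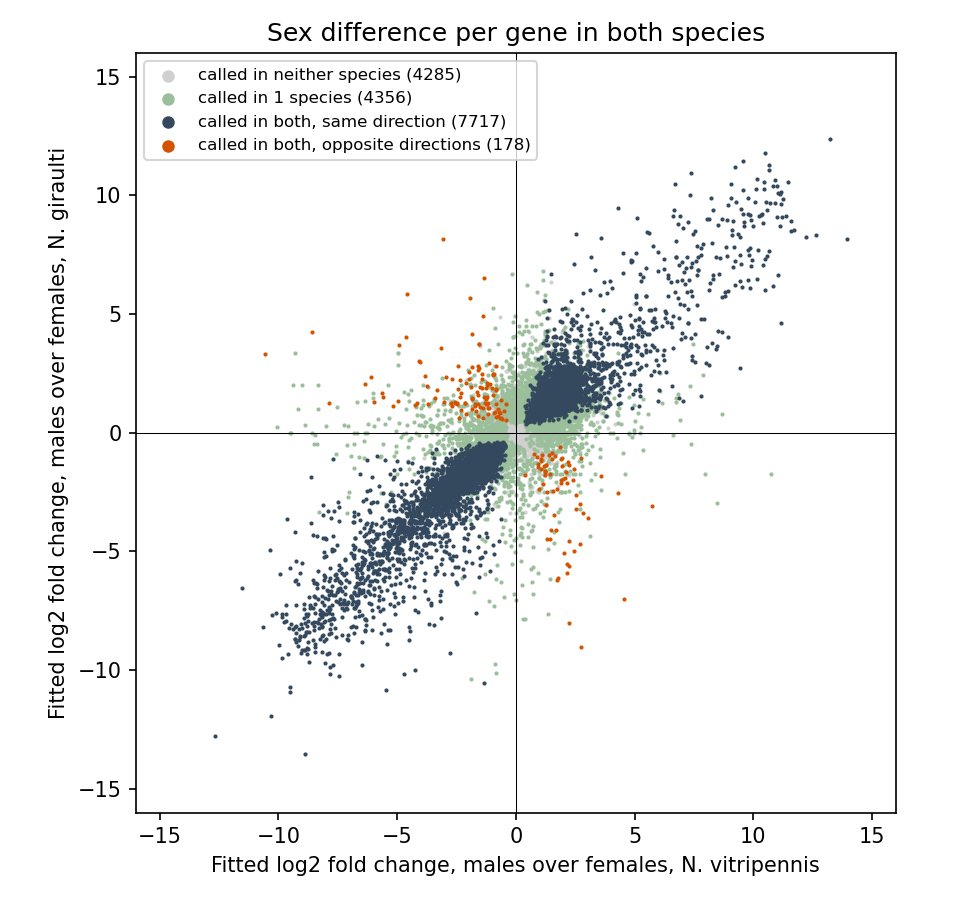
Fitted log2 fold change of males over females for each of the 16536 tested genes, N. vitripennis on the horizontal axis and N. giraulti on the vertical axis. Each point is a gene, coloured by whether it passed an adjusted p of 0.05 in both species, in 1 or in neither. The 178 genes called in opposite directions lie in the upper left and lower right, and fitted values of genes without reads in a sex depend on the model's prior.

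The difference between the species in the sex effect was tested directly with an interaction contrast. In 710 genes the sex effect was shifted toward males in N. giraulti and in 451 it was shifted toward females, together 7.02% of genes tested. With the replicate number as a block the counts were 1837 and 950. Of the 178 genes with opposite calls, 177 passed this test. This was nearly given by their selection, since opposite effects add up in the contrast, and is no separate support. Of the 1161 genes that passed, 727 (62.6%) had a smaller absolute sex difference in N. giraulti than in N. vitripennis.

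The genes named for the interaction were either expressed in the females of a single species or without reads in the males of a single species. Nasvi2EG023757 stood at 35.3 CPM ± 5.83 (SD, n = 3) in N. vitripennis females. It had 2 reads in all N. vitripennis male libraries, 3 in N. giraulti males and 0 in N. giraulti females, and the edgeR adjusted p of its interaction was 0.000684. Nasvi2EG004115 showed the same arrangement, with 46.8 CPM ± 8.94 in N. vitripennis females against 0.0465 CPM ± 0.0641 in their males, and 0.0771 ± 0.00877 and 0.0944 ± 0.0649 in N. giraulti females and males (edgeR adjusted p = 0.000103). Its log2 fold change of males over females was -10.06 (SE 0.63) in N. vitripennis and 0.24 (SE 0.70) in N. giraulti. Nasvi2EG000205 and Nasvi2EG000207 were higher in males of N. vitripennis, by a ratio of 6.67 (95% counting interval 6.05 to 7.36) and of 23.8 (20.6 to 27.7). Both had 0 reads in N. giraulti males, where they were at least 57.0-fold and at least 14.1-fold lower than in N. giraulti females, and the edgeR adjusted p of their interactions was 1.75e-05 and 3.42e-05.

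Nasvi2EG000206, whose identifier lies between those of the last pair and which was singled out after its values were seen, went the other way. It stood at 2088 CPM ± 1014 (SD, n = 3) in N. vitripennis males and 17895 CPM ± 5475 in N. giraulti males, against 18.6 CPM ± 5.53 and 40.2 CPM ± 8.83 in the females. Its log2 fold change of N. giraulti over N. vitripennis was 3.10 (SE 0.41) in males, with an edgeR adjusted p of 8.06e-05. Scaling changed the balance of the interaction: 61.15% of its calls were shifted toward males in N. giraulti with TMM scaling, 46.21% with upper-quartile scaling and 34.88% with library size alone. Leaving out replicate 2 or 3 of the N. vitripennis males or replicate 3 of the N. giraulti females lowered the 710 genes shifted toward males to 472, 447 and 462.

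**Figure D3:**
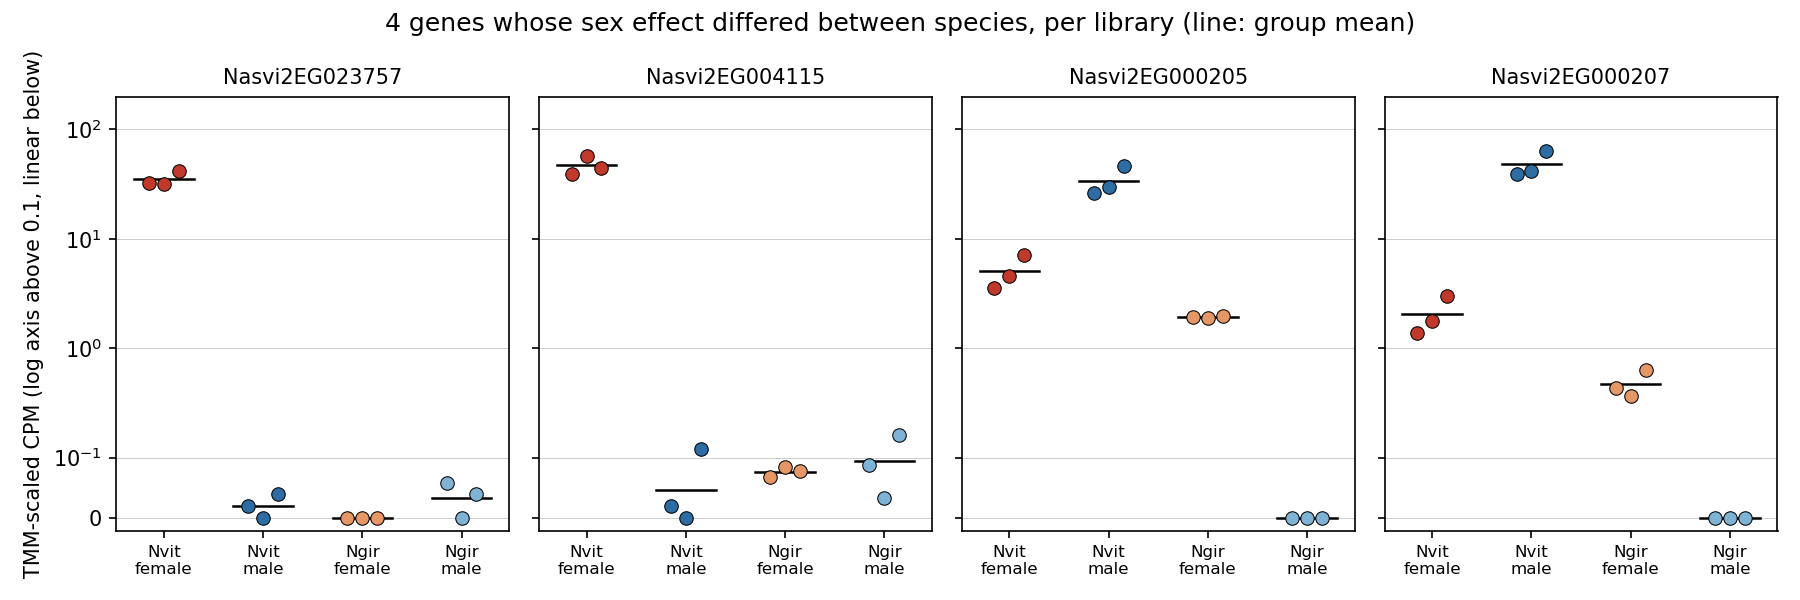
TMM-scaled CPM of 4 genes named for the interaction, per library, on an axis that is logarithmic above 0.1 and linear below it. Each point is a library (3 per group) and the line is the group mean. Nasvi2EG023757 and Nasvi2EG004115 stand at 35.3 and 46.8 CPM in N. vitripennis females, and Nasvi2EG000205 and Nasvi2EG000207 have 0 reads in the N. giraulti males.

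Between the species, within females, 2065 genes were higher and 3042 lower in N. giraulti. Within males 2483 were higher and 2742 lower, a balance that turned in each fit without a single male replicate, for example to 2630 and 1994 without replicate 3 of N. giraulti. With the replicate number as a block 5022 genes were lower in N. giraulti females, and at a mean of at least 1 CPM 1733 in females and 1762 in males. With only the compared groups in the fit the balance in females turned, to 2195 higher and 1931 lower. The species difference was called in both sexes for 3118 genes, of which 1305 were higher and 1652 lower in N. giraulti in both sexes and 161 had opposite directions. Independent lists would share 310.1 and 504.4 genes. At least 10-fold differences in both sexes were found in 313 genes higher and 582 lower in N. giraulti, and 42 genes at 1 CPM or more in both sexes of N. vitripennis had at most 3 reads in all N. giraulti libraries together, against 12 the other way.

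Calls between the species were more frequent among genes with a low mean over all libraries. This is partly given by the averaging, since a gene almost without reads in a species has a low mean for that reason. The filter could also keep a gene through a single group in which it is high. In the lowest quartile of mean expression, 873 genes were higher and 1210 lower in N. giraulti females, against 252 and 547 in the highest quartile. In males the highest quartile went the other way, with 516 genes higher and 310 lower in N. giraulti. The share of female calls that were higher in N. giraulti was 40.43% with TMM scaling, 54.51% with upper-quartile scaling and 54.69% with library size alone, and in males 47.52% with TMM scaling and 35.29% with library size alone. The reference that the reads were aligned to is not given in the sources used here, so these differences cannot be separated from a difference in how well reads of each species aligned.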

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

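Of the tests in this part, those of the shared batch, of dominant genes and other-sex RNA in the libraries numbered 1, of reads lost on a reference and of all splits that part the replicate pairs were chosen after the result was seen. What drew attention was a sex effect that differed between the species in a test of the difference itself. It was shifted toward males in N. giraulti in 710 genes and toward females in 451, a balance that turned under other scalings. Among them, the edgeR adjusted p of the interaction was 0.000684 for Nasvi2EG023757, 0.000103 for Nasvi2EG004115, 1.75e-05 for Nasvi2EG000205 and 3.42e-05 for Nasvi2EG000207. Of 100 splits of the species labels within each sex, drawn from 200, 3 called at least as many genes as the 1161 of the real split, itself included. The replicate numbers pair the libraries, however, and of all 32 splits that part every pair in both sexes, as the real one does, 2 called as many, a share of 0.0625. The highest other split, which is the second of these 2, called 6864 genes. It exchanged the species labels in females and left them in place in males, so it measured the species difference itself, which points to the structure of the samples and is no case of chance. The remaining 30 called at most 639. As that split belongs to the 32, they could hardly give a share under 0.05, and whether chance can be excluded is not decided by them.

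Sex effects were mostly smaller in N. giraulti: 62.6% of the 1161 interaction genes had a smaller absolute sex difference there, and 70.2% with the replicate number as a block. Other-sex RNA in the N. giraulti libraries would set a floor under sex-limited genes. The tables argue against it, since the 5th percentile of the level in the other sex, over abundant genes at least 10-fold higher in a sex of both species, was at most 0.191% of the level in the own sex. A uniform change in the share of a sex-limited tissue would move all genes of that tissue alike. The interquartile range of the interaction of the genes at least 10-fold higher in a sex was at least 2.5 times its median standard error. This argues against a change that moved all of them alike. The genes were not assigned to tissues, so a change in a single one of several tissues would spread them too and is not excluded. The median interaction was 0.375 log2 units for genes at least 10-fold higher in females and -0.789 for those higher in males. Both lie toward smaller sex effects in N. giraulti, so a changed share of a tissue, alone or beside differences of single genes, stays open. The lowest share over the scalings was 60.9%, above the bound of 60% set beforehand. Its 95% exact interval, 58.1 to 63.7%, was not part of that bound and treats genes as independent. As the interval reaches below 60%, scaling is not settled. Reads lost on a reference closer to N. vitripennis, taken up below for another pattern, were not tested for this one. They stay open, as does a difference between the species in sex-biased expression.

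Among genes at least 10-fold different in both sexes, more were lower than higher in N. giraulti, 582 against 313. Scaling does not account for it, since the ratio of lower to higher was at least 1.63 under each of the 4 scalings. Depth does not either: with each library thinned to the smallest total, genes at 1 CPM or more in N. vitripennis with at most 3 reads in N. giraulti outnumbered the reverse by at least 2.53 in either sex. The 2.53 is for females, with 215 against 85 genes, where the counts without thinning were 163 against 50. In males they were 242 against 64 with thinning and 191 against 46 without. Genes that met these limits in both sexes numbered 62 against 12 with thinning and 42 against 12 without, the latter a ratio of 3.5. The mean total count was also slightly higher in N. giraulti than in N. vitripennis. Such an excess is what reads lost on a reference closer to N. vitripennis would give. Expression that differs between the species could give it too. These cannot be told apart, because the reference is not given and each library holds a single species. Genes that the single set of identifiers lacks are also missing from these counts, which may be uneven between the species for that reason.

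The libraries numbered 1 stood apart in each of the 4 groups, with 3541 genes higher and 2733 lower than in numbers 2 and 3, against 20 genes between numbers 2 and 3. They were also the deepest of each group, but the mean correlation between libraries of the same number was 0.391 after thinning to the smallest total from 0.416 before. A few dominant genes would shift all others of a library by a common factor, while outside the 100 most abundant genes 3532 were higher and 2716 lower. The correlation without those 100 genes, tested first, could hardly have changed and is not used. Other-sex RNA was first tested by the sign of the other sex's 10-fold genes, which had medians above 0 in 2 of the 4 groups and near 0 in the rest, and decided nothing. The 1206 genes at least 2-fold lower in the libraries numbered 1 would need such RNA at about 0.5 of the library and a rise of at least 1 log2 unit, while the highest median rise was 0.172 and the highest upper quartile 0.62. A batch shared by libraries of a number stays open. The block on that number lowered the common dispersion by 57%, but this restates that libraries of a number deviate together and does not support a batch over another cause. No biological explanation was tested.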

How the results depend on the processing

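No named gene changed direction in the comparison it was named for. Which direction held more calls did turn. In the interaction 414 genes went toward males and 773 toward females in N. giraulti with library size alone, and 518 and 603 with upper-quartile scaling. In females 2552 genes were higher and 2114 lower in N. giraulti with library size alone, 2595 and 2166 with upper-quartile scaling, and 2195 and 1931 with only the compared groups in the fit. Between the sexes of N. giraulti 3506 were higher in males and 5258 in females with library size alone, 4497 and 4541 with no filter, 4328 and 4702 with only the compared groups, and the balance turned too in the 2-fold test and without replicate 2 of its females or 1 of its males. That of N. vitripennis turned with no filter, at a mean of 1 CPM, in the 2-fold test, in the 8 libraries and without each single replicate, that of the species in males without each single replicate, and that of the shared sex bias with the size factors and the Wald test of DESeq2, upper-quartile scaling and the block. Alternatives chosen after the data were seen were those without genes holding fractional counts and with the 8 libraries numbered 2 and 3, and both left the counts within 1.5 times. The size factors of DESeq2, its Wald test, the fit that was not robust and upper-quartile scaling did so too. The replicate block raised the interaction to 1837 genes toward males and 950 toward females in N. giraulti, the genes lower in N. giraulti females to 5022 and the opposite sex differences to 305. It ended the call of Nasvi2EG019966 and changed no other call of a named gene in the comparison it was named for. A mean of at least 1 CPM left 1733 genes lower in N. giraulti females and 1762 in males, since it tests fewer low genes, and the cause of the 1931 was not tested. With no filter the correlation of sex effects was 0.70969. The 500 most variable genes put 78.35% of the variance on component 1. A test against a 2-fold change, stricter by construction, left 2775 genes higher in males and 3429 in females in N. vitripennis, 1768 and 2519 in N. giraulti, 264 and 199 interaction genes, 1020 higher and 1376 lower in N. giraulti females, 1214 and 1532 in males, and 1174, 2216 and 37 genes shared toward males, toward females and opposite. Leaving out single replicates gave 447 to 674 interaction genes toward males in N. giraulti, lowest without replicate 3 of the N. vitripennis males. Relative to TMM, the median log2 fold change of all genes moved by up to 0.568 with upper-quartile scaling (sex, N. vitripennis). The 6 libraries of each pairwise comparison allow only 10 splits, too few for a share under 0.05: 1 of 10 splits, the real one, called as many genes, with 10745, 9401, 5107 and 5225 genes against 0 in the highest other split for the sex difference in N. vitripennis and N. giraulti and the species difference in females and males. Of genes simulated with a 4-fold interaction 36.4% were recovered, in a simulation that changed only 200 genes. A floor of 3 counts is 0.0584 to 0.126 CPM in a single library. The planned gene list tests and the genome-order test of neighbours were not run, for lack of matching names.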

Other observations

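The test of genes without reads beside an abundant neighbour was chosen after the result that suggested it was seen, and the other tests in this part before theirs. Genes with at least 1 CPM in a sex and 0 reads in the other were few. In N. vitripennis 24 genes with at least 1 CPM in males had 0 reads in females and 24 the reverse, and in N. giraulti 10 and 15. With up to 3 reads allowed in the other sex, the counts were 85 and 70 in N. vitripennis and 49 and 59 in N. giraulti. Between species, 60 genes with at least 1 CPM in N. vitripennis females had 0 reads in N. giraulti females, against 16 the other way. In males there were 53 against 9. Genes that the single set of identifiers lacks cannot appear on either side.

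A hypothesis was that sex-biased genes lie near each other. The gene positions are not known here, so the order of the identifiers stood in for the genome, which is an assumption. Without genes that share reads, 31.3% of neighbouring identifiers had the same sex call in N. vitripennis, against a mean of 22.8% in 1000 shuffles of the calls within quartiles of expression, a ratio of 1.376 (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). In N. giraulti the values were 24.7% and 17.8%. At 5 genes apart the ratio was 1.064 in N. vitripennis and 1.079 in N. giraulti (permutation p = 0.001 in each). At 500 apart it was 1.024 and 1.006 (permutation p = 0.047 and 0.35). Only neighbours were limited to pairs with nearby identifier numbers. Neighbouring identifiers may thus share sex bias. Reads that run from a gene into the next could give part of the excess between neighbours, and this was not tested. Such reads alone would not give the small excess at 5 genes apart. In N. vitripennis most shuffles were exceeded at 500 apart too, so a small excess need not come from nearness.

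Another hypothesis was that genes higher in males differ more between the species than genes higher in females. Over 20 bins of matched expression, the median absolute log2 species difference was larger by 0.11 for the 3732 genes higher in males in both species than for the 3985 higher in females (permutation p = 0.001, two-sided, the smallest that 1000 shuffles can give). It was larger by 0.12 among genes with a mean log2 CPM of at least 1, and by 0.105 without genes that share reads (permutation p = 0.004), where the largest value of the shuffles was 0.147. Faster divergence of genes higher in males would give this. A noisier estimate also raises an absolute difference, and noise within the matched bins was not compared. How well reads of each species aligned enters the species difference too, and it could not be compared between the 3732 and the 3985 genes.

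The last question came from Nasvi2EG000205 and Nasvi2EG000207, at 0 reads in N. giraulti males while Nasvi2EG000206 between them stood at 17895 CPM there. Their reads may have been assigned to the abundant neighbour. With these 3 genes left out, 0 of 31 cases of a gene with 0 reads in a group and at least 10 CPM in another had a neighbouring identifier at 1000 CPM or more in that group, against 1.59% of other cases (Fisher's exact test, two-sided, p = 1). At that rate 0.492 cases would be expected, so the test was too small to decide on reads assigned to an abundant gene with a neighbouring identifier.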
